A study of Piaractus mesopotamicus with 6 samples.

How the data were processed

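RNA sequencing libraries of 6 samples were compared, 3 of cultured primary muscle cells and 3 of fast-twitch muscle, from juvenile pacu of 12 to 20 g kept at 28 °C. Per the deposited series record, each cell isolation used muscle of 12 animals, the tissue came from 6 animals, and cells grew in DMEM with 10% fetal bovine serum and 1% antibiotics. RNA was extracted with TRIzol and poly(A) libraries were made with a stranded kit, per the labels' protocols. Neither says whether a tissue library pools animals.

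The submitters' processing notes name FastQC 0.11.8, Trimmomatic, Bowtie2, DESeq2 and the build GRCz11, with no role or order. The counting tool and the handling of reads that match several transcripts are not given in the sources used here. The deposited table, by the authors, gives normalised read counts for 71447 Trinity transcripts, that is counts divided by 1 size factor per library, each with a gene symbol or an Ensembl transcript identifier. Each value was a whole multiple of the library's smallest value above 0, within 0.01, for 100% of values in every library, so whole reads could be recovered. One read was worth between 0.391 and 0.439 in the cell libraries and between 1.98 and 2.67 in the tissue libraries. The floor of 3 counts was therefore higher in tissue, at 5.95 to 8.02, than in cells, at 1.17 to 1.32, and such floors cover counting error only. Of the transcripts, 2.64% to 4.86% were at 0 in the cell libraries and 12.6% to 23.6% in the tissue libraries. In 45.5% of the assembled genes with several transcripts the next transcript lay within 10% of the first, so reads shared between transcripts may have been counted more than once. Names covered 12266 rows by Ensembl identifier alone, and 6 rows had names turned into dates. No genome was used here, so no positions are given.

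Values were analysed on log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, as cells minus tissue over all 6 libraries, and Benjamini-Hochberg adjustment. Transcripts entered with a value of 10 or more in at least 3 libraries, which left 65662. A fold change on this scale understates the change of low genes. For named genes and lists, 1 transcript stood for each name ignoring case, the one with the highest mean, which gave 15550 names. The 21 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, which asks only whether a list's genes move one way on balance. None of the 15 lists past the camera threshold passed with an estimated correlation. For leukocyte markers and for Schwann and neuronal markers the estimate lay below 0.01, so a higher correlation did not end those calls. By fry all lists but smooth muscle and pericyte markers (adjusted p = 0.185) were past 0.05. The fry test sets a list against no change and not against the other names. Lists share some members, most often the fibroblast list, where 10 of 33 stand in another list. The table carries no annotated terms, so term enrichment was not run.

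Lists, tests, samples and the rule for named genes were set before the data were examined. The rule took the 8 largest rises and 8 largest falls among properly named genes past the threshold with fully separated libraries, the 2 highest members of each list and 1 further member with the largest change, and a fixed set of muscle regulators. The design had planned count models on recovered reads as alternatives. These were not run, and limma's voom weights on the recovered reads were used in their place, chosen after the data were seen. Other alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, 4 rescalings, a replicate block, a robust prior, summed names and leaving out each library, with the filter reapplied and, chosen after those counts were seen, over the same transcripts. Replicate pairs differed by far more than sampling noise (chi-square per degree of freedom from 58.6 to 235.7), so none was counted as a duplicate.

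The fit was tested on simulated counts for the 65662 transcripts, with dispersions taken from the real replicates, between 0.0487 and 0.581, and 200 transcripts changed. It recovered 10.4% of 2-fold, 67.2% of 4-fold and 86.4% of 8-fold changes, with 0.909% of calls false. In the real data 30949 transcripts were called, far more than the 200 changed here. Each simulated transcript took the median dispersion of transcripts of similar abundance, and no library was made to stand apart. These rates therefore hold for that setting and are not the rates of the real fit. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.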

Results

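RNA was sequenced from 2 kinds of sample from juvenile pacu (Piaractus mesopotamicus), a South American freshwater fish: 3 libraries of primary muscle cells grown in serum-containing medium and 3 libraries of the fast-twitch epaxial muscle. The table held normalised read counts of 71447 assembled transcripts. The whole reads recovered from it numbered 105795157 to 115224600 per cultured cell library and 118183731 to 124752600 per tissue library. The labels name separate libraries but not which animals or cultures each came from, so the p-values speak for these libraries only. They rest on a transcript's own spread between libraries, with 4 residual degrees of freedom. Added to it is a prior variance taken from transcripts of similar abundance, with 2.93 prior degrees of freedom.

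Cultured cells and muscle differed in many of the genes measured, with the contractile and glycolytic genes of the fibre lower in culture and genes of matrix, cytoskeleton and cell division higher. Here a gene that rose or fell was higher or lower in cells than in tissue, as no library follows the same cells over time. The tissue also held transcripts of other cells, such as blood cells. A different mix of cells and a change of expression within cells therefore cannot be told apart. Parvalbumin pvalb4, a calcium buffer of fast fibres, averaged 3056700 ± 1104700 normalised counts in tissue and 289 ± 251 in cells (SD, n = 3 each). Fibronectin fn1b, a matrix protein, averaged 326810 ± 72865 in cells and 1696 ± 651 in tissue (SD, n = 3 each). Of 65662 transcripts tested with limma, 18001 were higher and 12948 lower in cells at an adjusted p below 0.05, of which 16939 and 11912 changed by a log2 of 1 or more. Counted by name, 4744 of 15550 names were higher and 3374 lower, and the libraries of the groups did not overlap for 66.3% of names, against 10% by chance. Higher calls made up 58.2% of the calls on the deposited scale and 91.6% after scaling to equal totals, which moved the median change of all names from 0.59 to 3.10. With cell library 1, 2 or 3 left out and the filter reapplied, which a transcript present in cells alone then cannot pass, lower transcripts outnumbered higher ones. The higher transcripts were then 10084, 9030, 9449 and the lower ones 11341, 10767, 11069, with 47.1%, 45.6% and 46.1% of calls higher. The higher names were 3041, 2765, 2895 and the lower ones 3006, 2842, 2892. Over the same transcripts higher ones led without cell library 1, 2 or 3, at 12808, 11964 and 12245 against 11299, 10750 and 11008 lower (53.1, 52.7 and 52.7% higher), while with cell library 1 alone 39.9% of calls were higher.

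The libraries correlated at a median Pearson r of 0.936 within cultured cells, 0.819 within tissue and 0.386 between the groups, across the tested transcripts on the log2 scale, the last being 0.190 at a filter of 50. A gene with several transcripts counts more than once in these values. The first principal component held 76.5% of the variance and parted the groups. The second held 12.7% and set tissue library 1 apart from tissue libraries 2 and 3. The 10 highest transcripts took 27.4% ± 1.33 of the tissue signal and 9.07% ± 1.01 of the cell signal (SD, n = 3 each), with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. With transcripts of the same name summed these shares were 50.5% and 29.9%.

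The fast sarcomere genes were lower in culture than in tissue almost as a block. Of 68 measured members, 65 fell, none rose and 3 did not pass the test, and 66 fell adjusted over the list alone. The list's median log2 change was -10.73 (adjusted p = 1.03e-28 by camera, and adjusted p = 0.221 with an estimated correlation). Fast myosin heavy chain myhz1.1 averaged 396 ± 349.8 in cells and 2722300 ± 219590 in tissue (log2 change -14.13, SE 1.49, adjusted p = 0.000292). The regulatory light chain mylpfa changed by -13.83 (adjusted p = 0.000295) and myosin-binding protein mybpc2b by -14.49 (adjusted p = 0.000183). In the slow and cardiac-type list 15 of 19 members fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 3.83e-08 by camera, and adjusted p = 0.291 with an estimated correlation). Myoglobin mb, the oxygen store of muscle, fell by 11.02 on the log2 scale (adjusted p = 2.92e-05), MYH6 changed by -13.92 and myoz2a by -10.91. Of the excitation-contraction coupling genes, 37 of 43 fell and 2 rose, again the same counts adjusted over the list alone (adjusted p = 1.39e-15 by camera, and adjusted p = 0.221 with an estimated correlation). The parvalbumins pvalb4, pvalb3 and pvalb2 changed by -15.64, -14.65 and -14.38 (adjusted p = 0.00121, 0.000384 and 0.000241). Myosins and parvalbumins are families of near-identical copies whose reads the counting may split, so single members are uncertain. The tested transcripts of these parvalbumins belong to the same assembled gene, so they are not independent results. The changes of the myosin, myosin-binding and parvalbumin genes named here lay at -12.73 to -11.94 without cell library 1, -17.12 to -14.64 without library 2 and -17.09 to -14.91 without library 3. Relative to all names, the fast sarcomere median of -11.32 was -10.70 without cell library 1, and the slow and cardiac-type median of -9.04 was -9.67 without cell library 3. The coupling genes that rose numbered 0 without any 1 of the cell libraries, and 1, 3 and 1 without tissue library 1, 2 or 3, and the slow list's 1 rise ended without cell library 2 or 3.

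**Figure D1:**
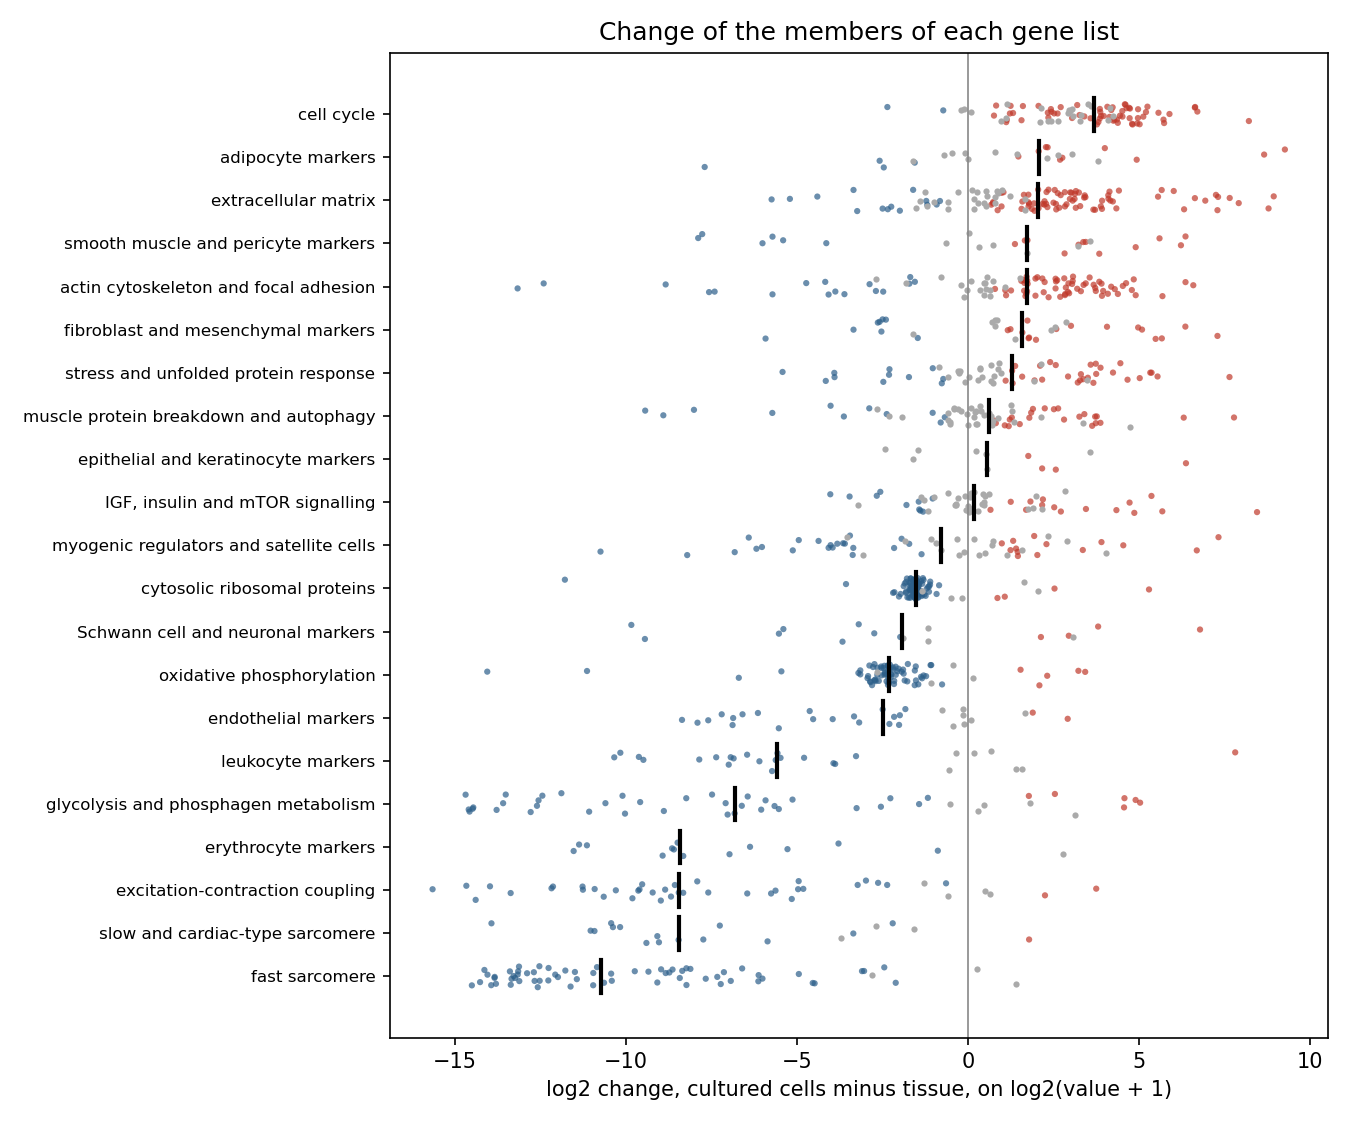
The x axis gives the log2 change between cultured cells and tissue on log2(value + 1), and each point is 1 member of the list named on the y axis, red if higher and blue if lower in cells at an adjusted p below 0.05 and grey otherwise. Black bars are list medians, which run from -10.73 for fast sarcomere to 3.68 for cell cycle; under equal totals the medians of 5 lists change sign, those of oxidative phosphorylation, ribosomal proteins, endothelial markers, Schwann and neuronal markers and myogenic regulators.

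Enzymes of glycolysis and of the creatine kinase system fell, with 36 of 47 members lower and 6 higher (36 and 7 adjusted over the list alone; adjusted p = 2.55e-12 by camera, and adjusted p = 0.169 with an estimated correlation). Muscle creatine kinase ckmb averaged 908 ± 474 in cells and 3115600 ± 859780 in tissue (log2 change -11.88, SE 0.51, adjusted p = 1.37e-05). Aldolase aldoab changed by -14.45, glycogen phosphorylase pygma by -14.68, gapdh by -14.47, pgam2 by -14.56 and enolase ENO3 by -14.59, with adjusted p between 0.000132 and 0.000362. These 5 changes lay at -12.99 to -12.55 without cell library 1, -15.74 to -15.36 without library 2 and -15.74 to -15.26 without library 3. Of the list, 13 were higher and 31 lower under equal totals. The 6 members that rose, named after their values were seen, were gpia, gapdhs, pgam1a, pkma, aldocb and hk1.

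Genes of oxidative phosphorylation and cytosolic ribosomal proteins were lower in culture on the deposited scale and under every rescaling but equal totals. The factors of TMM, upper quartile and median of ratios lay close to the deposited ones, at 2.47, 2.52 and 2.59 against 2.46 for cell library 1. These rescalings are therefore no independent check of the direction. Of 78 oxidative phosphorylation genes 69 fell and 5 rose (70 and 5 adjusted over the list alone), with a median of -2.29 (adjusted p = 1.34e-22 by camera, and adjusted p = 0.223 with an estimated correlation). The ATP synthase subunit atp5f1b averaged 8377 ± 643 in cells and 45352 ± 3800.1 in tissue, the muscle nucleotide carrier slc25a4 changed by -14.04 and the muscle subunit cox6a2 by -11.13. Of 90 genes matched as ribosomal proteins, which by their names take in several S6 kinases, 81 fell and 4 rose, the same counts adjusted over the list alone, with a median of -1.50 (adjusted p = 2.7e-16 by camera, and adjusted p = 0.388 with an estimated correlation). The abundant rplp0 and rps2 changed by -1.68 and -1.66 (adjusted p = 0.00519 and 0.0055), and RPL3L, a muscle form, by -11.78. After scaling to equal totals both directions turned, with medians of 0.25 for oxidative phosphorylation and 1.04 for ribosomal proteins, where the camera call for the latter ended, and atp5f1b, rplp0 and rps2 turned to 0.10, 0.87 and 0.88. The counts were then 26 higher and 6 lower for oxidative phosphorylation and 84 and 2 for ribosomal proteins. On the deposited scale 2 ribosomal proteins rose without cell library 1 or 2. Without cell library 1 or 3 slc25a4 changed by -12.64 and -15.03, and without tissue library 1 RPL3L by -11.15.

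The regulators of muscle identity moved in both directions, with a median log2 change of -0.77 that turned to 1.71 under equal totals. Of 55 myogenic and satellite cell genes 14 rose, 22 fell and 19 did not pass the test (15 and 25 adjusted over the list alone; adjusted p = 0.0237 by camera, and adjusted p = 0.433 with an estimated correlation). The satellite cell factor pax7b rose from 423 ± 118 in tissue to 1036 ± 105 in cells (log2 change 1.33, SE 0.24, adjusted p = 0.00387), while pax7a (log2 change -0.10, adjusted p = 0.965) and myf5 (log2 change 0.17, adjusted p = 0.779) did not pass. The determination factor myod1 fell from 1191 ± 115 to 122 ± 103 (log2 change -3.64, SE 0.59, adjusted p = 0.00222). Under equal totals myod1 did not pass (adjusted p from 0.000466 to 0.108 over the alternatives). Transcripts of myf6, a factor of mature fibres, changed by -6.02 (adjusted p = 0.00298). The differentiation factor myog had 44.2, 133 and 326 normalised counts in the cultured cell libraries and 463 ± 136 in tissue (log2 change -1.84, adjusted p = 0.0637). The fusion gene mymk had 23.5, 45.2 and 131 in the cell libraries and 0, 31.7 and 0 in the tissue libraries (log2 change 4.05, or 3.21 to 5.73 without 1 library, adjusted p = 0.0613). Both passed with voom weights and at pseudocount 5 (myog adjusted p from 0.0163 to 0.384 over the alternatives, mymk adjusted p from 0.00363 to 0.534 over the alternatives), and under equal totals myog turned to 0.69. Desmin desma, mef2aa and the growth inhibitor mstnb changed by -6.40, -3.95 and -4.01 (adjusted p = 0.000344, 1.03e-05 and 8.16e-05). The homeobox gene six4a was listed at 0 in all 3 cell libraries and was at least 1380.1-fold lower there, against a floor of 3 counts per library. Of the list, 31 were higher and 12 lower under equal totals. Without cell library 1 the changes of myod1 and desma were -3.04 and -5.62, and without cell library 3 those of myod1, desma and myf6 were -4.31, -7.17 and -6.96, that of myf6 being -5.39 without tissue library 1. Of the other genes fixed in advance, pax3a and igf1 were below the filter and mymx was not among the names.

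Genes of cell division rose in culture. Of 88 members 63 rose and 2 fell (70 and 2 adjusted over the list alone), with a median of 3.68, or 3.55 with members at 0 in a group set at their bound (adjusted p = 3.31e-08 by camera, and adjusted p = 0.291 with an estimated correlation). The proliferation marker mki67 averaged 661 ± 150.1 in cells and 77.8 ± 45.3 in tissue (log2 change 3.20, SE 0.43, adjusted p = 0.000908). The replication clamp pcna changed by 2.44 (adjusted p = 0.0125, not past the test without cell library 2, with adjusted p from 0.000311 to 0.295 over the alternatives), the cytokinesis gene anln by 8.21 (adjusted p = 0.000666) and hmgb2a by 0.77 (adjusted p = 0.00579), while uhrf1 did not pass (log2 change -0.11, adjusted p = 0.675). Without tissue library 1, pcna changed by 1.72 and anln by 6.92, and anln by 8.96 without tissue library 2. The list's median relative to all names, 3.10, was 2.48 without tissue library 1, and 41 members rose without cell library 2, while 1 fell without cell library 1, 2 or 3 or tissue library 2 or 3. Under equal totals 88 of 90 were higher and none lower.

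Matrix genes rose as well, with 74 of 113 higher and 14 lower (75 and 15 adjusted over the list alone; adjusted p = 1.5e-07 by camera, and adjusted p = 0.142 with an estimated correlation). Besides fn1b (log2 change 7.65, SE 0.38, adjusted p = 2.04e-05), the gelatinase mmp9 rose by 8.94 (adjusted p = 2.84e-05). The fibrillar collagens col1a2 (log2 change 0.85, SE 0.66, adjusted p = 0.316) and col1a1b (log2 change 0.80, SE 0.45, adjusted p = 0.181), 2 of the 3 matrix genes with the highest means, did not pass the main test. In both, every cell library lay above every tissue library. The tested transcripts of both belong to the same assembled gene, so they are not independent results. Both passed with voom weights, with a robust prior and under equal totals (col1a2 adjusted p from 9.81e-05 to 0.835 over the alternatives, col1a1b adjusted p from 4.22e-05 to 0.702 over the alternatives). The robust prior left both changes as they were and gave limma adjusted p = 0.00387 for col1a2 and 0.00592 for col1a1b. Their failure in the main test therefore rests on its prior variance. In the actin and focal adhesion list 61 of 96 rose and 17 fell (64 and 18 adjusted over the list alone; adjusted p = 0.000166 by camera, and adjusted p = 0.431 with an estimated correlation), and the camera call ended under equal totals. The actins acta2 and actb1 fell (-5.71 and -2.47, the latter at 0.0688 under equal totals and not past the test without cell library 2 or 3, with adjusted p from 3.54e-06 to 0.84 over the alternatives), and as near-identical copies of the skeletal actins they may hold shared reads. Their tested transcripts also belong to the same assembled gene, so they are not independent results. The highest pdlim5b transcript changed by -13.16 (adjusted p = 6.6e-06), and all pdlim5b transcripts summed by -0.18 (adjusted p from 2.59e-07 to 0.49 over the alternatives), so the gene as a whole did not pass. The cell mean of that highest transcript, 0.728, lay under the floor of 3 counts. Under equal totals 99 of 114 matrix genes were higher and 4 lower, and 79 and 10 of the actin list. The genes with the largest rises outside the lists were bmp8a, sall1a, ccdc3a, epdl1, frmd4bb and dkk2. On 2 reads in 1 tissue library, ccdc3a was higher by 756-fold (95% counting interval 209 to 6239.6) and dkk2 by 504-fold (95% counting interval 139 to 4158), and epdl1 and frmd4bb averaged 1301 ± 1039.6 and 1125 ± 85.5 in cells and 2.64 ± 4.58 and 3.57 ± 6.18 in tissue, with values above 0 in tissue library 2 and tissue library 1 alone. The genes bmp8a and sall1a were listed at 0 in all tissue libraries and at least 122-fold and 78-fold higher in cells against that floor.

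**Figure D2:**
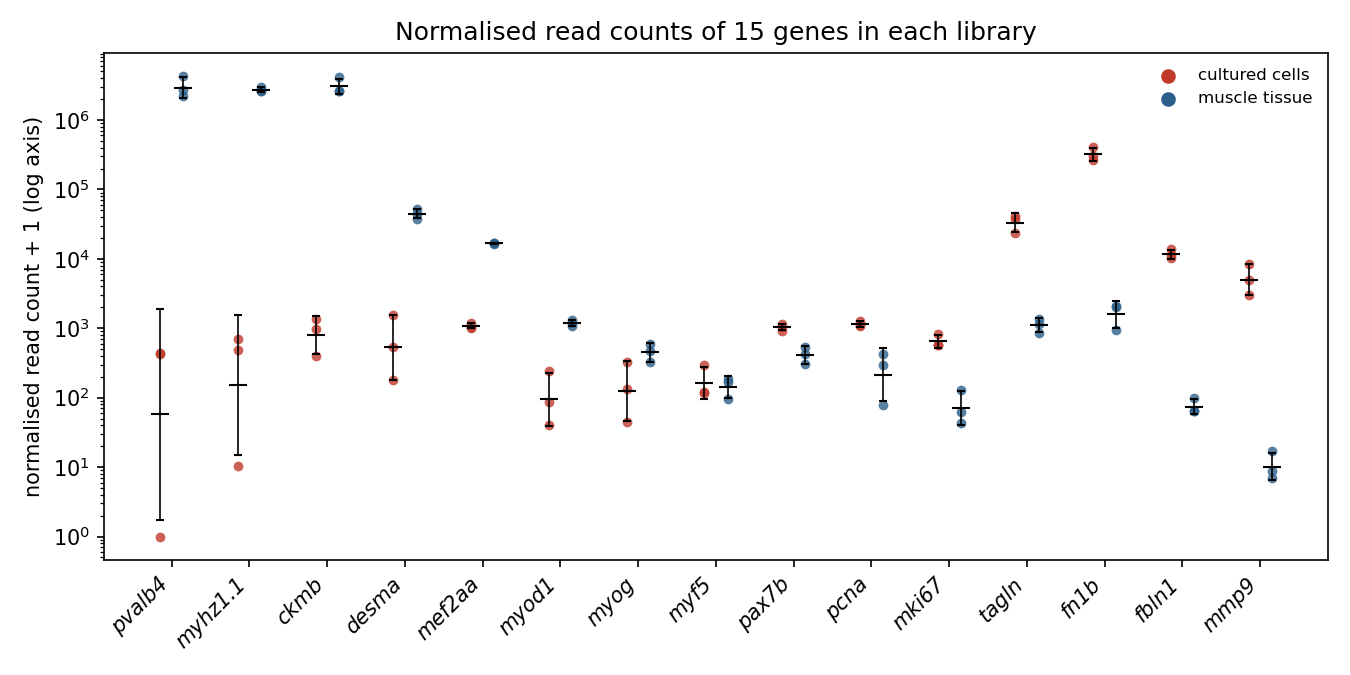
Each point is the normalised read count plus 1 of a gene in 1 library, on a log axis, for cultured cells in red and tissue in blue, and bars give the mean and SD on the log2 scale (n = 3). The cell libraries lie below tissue for pvalb4, myhz1.1 and ckmb and above it for tagln, fn1b, fbln1 and mmp9.

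Growth signalling, protein breakdown and stress genes moved in both directions, and on balance up by fry (adjusted p = 0.00666, 0.00269 and 0.00592). That test is against no change, while the median log2 change of all names was 0.59. An upward call by it therefore does not set a list apart from other names. Relative to all names the medians of these lists were -0.40, 0.04 and 0.71. In the IGF, insulin and mTOR list 15 of 55 rose and 10 fell, the same counts adjusted over the list alone, the median being 0.18, the mean 0.64 and camera's direction down (adjusted p = 0.762). The growth factor igf2b rose from 21.6 ± 14.2 to 974 ± 322 (log2 change 5.69, SE 0.68, adjusted p = 0.000514), and igf2a did not pass (log2 change -0.06, adjusted p = 0.948). The binding protein igfbp5b changed by -1.79 and rps6 by -1.43, and igfbp6a, at 0 in all tissue libraries, was at least 64.9-fold higher in cells. Of the breakdown and autophagy genes 23 of 68 rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.431). The ubiquitin ligase trim63a fell from 3063 ± 1703 to 4.37 ± 4 (log2 change -9.43, SE 0.94, adjusted p = 0.00023) and fbxo32, another atrophy ligase, did not pass (log2 change -0.51, adjusted p = 0.545), while fstl1b and ubb rose by 3.41 and 0.77. Of the stress genes 29 of 61 rose and 11 fell (31 and 11 adjusted over the list alone; adjusted p = 0.0345 by camera, and adjusted p = 0.578 with an estimated correlation). The camera call for stress genes also ended under equal totals, with voom weights and without tissue library 1. The chaperone hspa8 changed by 1.31 and atf4a by -0.76 (adjusted p = 0.00494 and 0.0456). The cystine transporter slc7a11 was at 0 in all tissue libraries and had 1295, 85.6 and 71 in cells. The call of atf4a ended without any 1 of the cell libraries (adjusted p from 0.000102 to 0.337 over the alternatives). Without tissue library 1 igf2b changed by 4.93 and trim63a by -10.05, the latter by -8.46 and -10.03 without cell library 1 or 3. Under equal totals 49 growth signalling genes were higher and 1 lower, breakdown genes 57 and 6, and stress genes 52 and 3. On that scale rps6, igfbp5b and atf4a turned to 1.11, 0.75 and 1.78.

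Markers of blood cells fell in culture, those of endothelial cells fell on the deposited scale, and those of nerve, mesenchymal, smooth muscle and pericyte cells were mixed. The endothelial median of -2.49 and the Schwann and neuronal median of -1.93 turned to 0.0915 and 1.24 under equal totals. Erythrocyte markers fell in 13 of 14 members, with the same count adjusted over the list alone (adjusted p = 2.37e-07 by camera, and adjusted p = 0.291 with an estimated correlation). The globin hbaa2 changed by -11.52, hbba2 by -11.13 and ank1a by -11.36. The cell means of hbaa2 and hbba2, 0.583 and 0.876, lay under the floor of 3 counts, so the size of their changes rests on the pseudocount. In the tissue libraries ank1a had 10700, 12969 and 14878 and hbaa2 had 1091, 10349 and 7858, so ank1a did not vary with this globin. Leukocyte markers fell in 19 of 26 and rose in 1, the same adjusted over the list alone (adjusted p = 6.48e-08 by camera, and adjusted p = 0.0708 with an estimated correlation). The antigen-presentation genes cd74a and cd74b changed by -10.33 and -7.35, and lcp1, at 0 in all cell libraries, was at least 925-fold lower. The cell mean of cd74a, 0.974, also lay under the floor of 3 counts. Endothelial markers fell in 20 of 29 (21 adjusted over the list alone; adjusted p = 2.7e-06 by camera, and adjusted p = 0.169 with an estimated correlation), with sox17, on 3 reads in cell library 3, lower by 1079-fold (95% counting interval 369 to 5234), while kdrl (log2 change 0.08, adjusted p = 0.802) and mmrn2b (log2 change -0.76, adjusted p = 0.0616) did not pass. With voom weights and under TMM, upper quartile and median-of-ratios rescaling mmrn2b passed as lower (adjusted p from 0.0011 to 0.236 over the alternatives), and under equal totals it turned to 1.78. Schwann and neuronal markers fell in 8 of 16 and rose in 4 (9 and 4 adjusted over the list alone; adjusted p = 0.0341 by camera, and adjusted p = 0.221 with an estimated correlation). The camera call of this list also ended under 5 other settings. Among its members stood pmp22b at -2.73 (not past the test under equal totals, with adjusted p from 1.3e-05 to 0.439 over the alternatives), TUBB3 at 3.81 and the myelin gene mbpa, at 0 in all cell libraries, at least 734-fold lower. Fibroblast markers rose in 16 of 33 and fell in 8, the same adjusted over the list alone (camera adjusted p = 0.126), fbln1 averaging 11813 ± 1795 in cells and 75 ± 19.2 in tissue (log2 change 7.30, SE 0.22, adjusted p = 7.13e-06). Smooth muscle and pericyte markers rose in 12 of 25 and fell in 6 (14 and 6 adjusted over the list alone, camera adjusted p = 0.278), with tagln at 4.91, acta2 at -5.71 and rgs5a at -7.88. The value of acta2 may hold reads of the skeletal actins. Adipocyte markers rose in 10 of 25 and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.334), with lepb at 9.27, scd at 2.33 and fabp11a at 0.01 (adjusted p = 0.976). Epithelial markers rose in 4 of 11 and fell in none, the same adjusted over the list alone (camera adjusted p = 0.301), with krt4 at 2.57 and jupa at 2.17 (not past the test without cell library 2 or 3, with adjusted p from 0.000212 to 0.338 over the alternatives). On 2 reads in tissue library 3, the adhesion gene epcam was higher in cells by 106-fold (95% counting interval 29.4 to 878). The epithelial median lay at -0.04 relative to all names although camera's direction was up. Without tissue library 1 or 2 hbaa2 changed by -12.53 and -10.91 and hbba2 by -12.14 and -10.51, without tissue library 1 or 3 lepb by 10.32 and 8.17, and without cell library 1 or 3 ank1a by -10.64 and -12.29. Under equal totals the members higher and lower were 9 and 10 for endothelial, 6 and 5 for Schwann and neuronal, 6 and 18 for leukocyte, 24 and 2 for fibroblast, 21 and 1 for adipocyte and 9 and 0 for epithelial markers. Of the genes named as not past the test, uhrf1, igf2a, fbxo32, fabp11a, kdrl, myf5, mmrn2b and mymk passed as higher under equal totals.

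The fibre genes were unevenly present among the cultured cell libraries. Counts of pvalb4 were 0, 442 and 425 in cell libraries 1, 2 and 3, those of myhz1.1 9.39, 486 and 691, and those of pygma 0, 83 and 81.9. Over the 57 names with a tissue mean of 50000 or more that were nearly absent from library 1, library 2 held 1 part in 5303 of the tissue value at the median and library 3 held 1 part in 4108. Fold changes of such genes therefore rest on which cell library is taken.

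**Figure D3:**
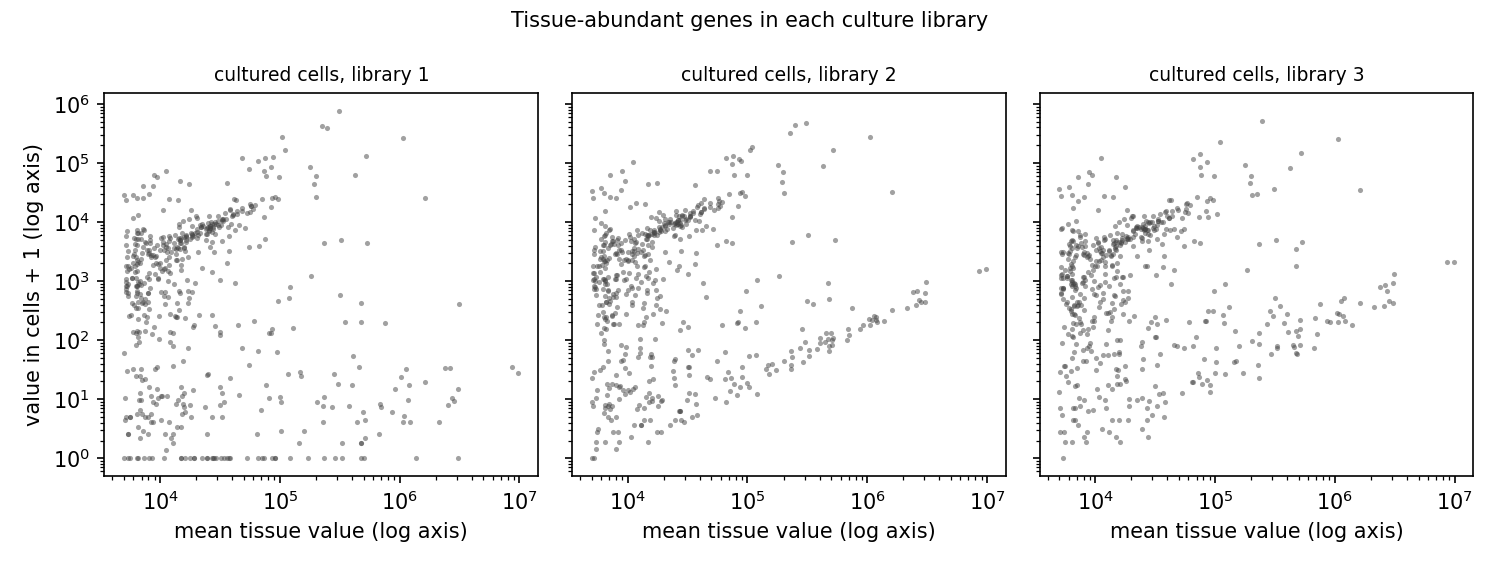
Each point is 1 of 546 names with a mean tissue value of 5000 or more, with that mean on the x axis and its value plus 1 in a cultured cell library on the y axis, both on log axes. There is 1 panel per library. Libraries 2 and 3 show a lower band that runs parallel to the tissue value, near 1 part in 5303 and 1 part in 4108, and library 1 does not.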

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

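The voom weights, the fit of cultured cell library 1 alone and leaving out libraries over the same transcripts were chosen after the data were seen, the other alternatives before. The planned count models were not run. Scaling to equal totals gave 53811 transcripts higher and 4965 lower, and 12710 names higher and 1225 lower, because it sets the totals of cells and tissue level where the deposited factors leave them unequal. The other rescalings, pseudocounts, filters, the robust prior and voom kept all 4 counts within 1.5 times. Leaving out 1 library was first fitted with the filter reapplied, and the version over the same transcripts took its place after those counts were seen. Over the same transcripts it gave 11964 to 20095 higher transcripts. With the filter reapplied, leaving out cell library 1, 2 or 3 gave 10084, 9030, 9449 higher transcripts and 3041, 2765, 2895 higher names, against 12808, 11964, 12245 and 3492, 3260, 3350 over the same transcripts, so most of the fall came with the loss of a library and the rest with the filter. Cell library 1 alone against tissue gave 4037 transcripts higher and 6089 lower, and 1020 names higher and 1596 lower, with 1 sample assumed to vary like the tissue libraries. The replicate block gave 17062 higher and 11855 lower, and deviations of same-numbered libraries correlated at -0.063, -0.045 and -0.017. No library correlated best with its own number, but other pairs were as weak, at -0.028 to 0.058. Deviations within groups of 3 also depend on each other. These values therefore cannot show whether equal numbers share animals or days.

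With an estimated correlation all 15 list calls ended, at unchanged medians relative to all names: fast sarcomere -11.32, slow and cardiac-type sarcomere -9.04, excitation-contraction coupling -9.03, glycolysis and phosphagen metabolism -7.40, oxidative phosphorylation -2.88, myogenic regulators and satellite cells -1.36, cell cycle 3.10, extracellular matrix 1.47, actin cytoskeleton and focal adhesion 1.15, stress and unfolded protein response 0.71, cytosolic ribosomal proteins -2.09, endothelial markers -3.07, leukocyte markers -6.18, erythrocyte markers -8.99, Schwann cell and neuronal markers -2.52. The estimated correlation was -0.00497 for leukocyte and -0.0390 for Schwann and neuronal markers, below the preset 0.01. A higher correlation therefore did not end those calls. For the other lists past the threshold it ran from 0.0223 for extracellular matrix to 0.712 for ribosomal proteins. For stress genes the call also ended under equal totals (0.73) and voom (0.74) and without tissue library 1, with 0.57 to 0.78 when a library was left out. Under equal totals it ended for actin and focal adhesion (1.17) and ribosomal proteins (-2.06). For Schwann and neuronal markers it ended without a filter (-2.17), at a filter of 50 (-2.84), with summed names (-2.19) and voom (-2.62) and without tissue library 1, with -2.81 to -2.16 when a library was left out. Of the 6 lists not past the threshold, breakdown and epithelial genes changed sign and the other lists did not. Breakdown and autophagy had -0.0121 at pseudocount 5, -0.00942 without a filter and -0.0603 under equal totals, and -0.16 to 0.0971 without 1 library. Epithelial markers had 0.0342, 0.52, 0.0631, 0.59 and 0.21 at pseudocount 5, no filter, filter 50, equal totals and summed names, 0.24 with cell library 1 alone, and -0.10 to 0.28 without 1 library.

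The median correlation between groups was 0.190 at filter 50, 0.447 without a filter and 0.442 at pseudocount 5, which also gave 0.955 within cells and 0.874 within tissue. The 10 highest took 29.9% of the cell and 50.5% of the tissue signal with summed names, and the 100 highest took 32.5% and 66.2%. Log2 changes of opposite sign under equal totals were actb1 0.0688, atf4a 1.78, atp5f1b 0.10, fbxo32 1.99, igf2a 2.42, igfbp5b 0.75, mmrn2b 1.78, myog 0.69, pax7a 1.79, rplp0 0.87, rps2 0.88, rps6 1.11, uhrf1 2.43. Genes short of the threshold on the deposited scale also changed sign under TMM (fabp11a -0.0734, kdrl -0.000875), upper quartile (fabp11a -0.0751, kdrl -0.00259), median of ratios (fabp11a -0.13, kdrl -0.0621), voom (fabp11a -0.0813, kdrl -0.0154), pseudocount 0.5 (pax7a 0.14), summed names (fabp11a -0.23, pax7a 1.5) and cell library 1 alone (fabp11a -0.19, fbxo32 0.29, kdrl -0.41, myf5 -0.23). Without 1 library they ranged as fabp11a -0.29 to 0.21, fbxo32 -0.91 to 0.0721, igf2a -0.50 to 0.40, kdrl -0.0927 to 0.33, myf5 -0.27 to 0.42, pax7a -1.96 to 1.05, uhrf1 -0.19 to 0.0354. Calls ended for atf4a at pseudocount 0.5, under the replicate block and without tissue library 3 or any cell library, for actb1 under the block and without cell library 2 or 3, for jupa without cell library 2 or 3, for pcna without cell library 2, for myod1 and pmp22b under equal totals, and for 23 named genes with cell library 1 alone. Calls came for mmrn2b under TMM, upper quartile, median of ratios, voom and without tissue library 3, for myog at pseudocount 5, under the block, with voom, without cell library 3 and with cell library 1 alone, for mymk at pseudocount 5, with voom, under equal totals and without tissue library 2, for col1a2 and col1a1b under equal totals, voom and the robust prior, and, as higher under equal totals, for fabp11a, kdrl, myf5, uhrf1, mmrn2b, igf2a and fbxo32. The gene pdlim5b stood at -0.18 with summed names, where other transcripts of that name, higher in cells, offset the one tested. Except for equal totals, and for the robust prior, which alters only the prior variance, the cause of these shifts was not tested. Tissue values rest on a coarser step per read, which limits what can be seen of genes near 0 there.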

Other observations

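The gene families of the next paragraph, the HOX test, the counts without 1 library, the counts of splits and the test of the ratio's spread were chosen after the values they rest on were seen. The tests of the mid-abundance sums and of the shared batch were set down before theirs.

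Genes of cholesterol synthesis and uptake were higher in culture in 21 of 24 measured members and lower in none on the deposited scale (1 was lower under TMM, upper quartile and median-of-ratios rescaling), with a median log2 change of 5.11 (camera adjusted p = 1.49e-07 with a preset correlation and adjusted p = 0.0996 with an estimated correlation). The rate-limiting reductase hmgcra changed by 8.84, lss by 7.60, cyp51 by 6.03 and the regulator srebf2 by 3.14, while hmgcrb had a change of -1.53 (adjusted p = 0.0559). Cathepsins, proteases of the lysosome, were higher in 7 of 11 and lower in 1 (camera adjusted p = 0.00891 with a preset correlation and adjusted p = 0.108 with an estimated correlation), with ctsla at 3.74 and ctsk at 3.72. Ligands of the BMP and TGF-beta family were higher in 8 of 16 (camera adjusted p = 0.00716 with a preset correlation and adjusted p = 0.103 with an estimated correlation), and bmp3, bmp2a, gdf10a and INHBB were at 0 in all tissue libraries with cell means of 341, 157, 136 and 229. Fatty acid oxidation genes were lower in 18 of 26 (camera adjusted p = 1.31e-07 with a preset correlation and adjusted p = 0.103 with an estimated correlation), and the muscle carnitine transferase cpt1b changed by -9.32. Of 35 circadian clock genes 16 were lower and 4 higher (camera adjusted p = 0.000576 with a preset correlation and adjusted p = 0.108 with an estimated correlation), with nr1d1 at -8.22 and per3 at -3.85. The nfil3 genes went both ways, with nfil3 at 5.37, nfil3-5 at 4.69 and nfil3-6 at -4.38, and arntl1a was at 2.38. No time of sampling entered the test. Under equal totals the medians of fatty acid oxidation and clock genes turned to 0.59 and 1.65, with 14 higher and 5 lower for fatty acid oxidation and 19 and 3 for the clock, and all 16 ligands and all 11 cathepsins were higher. Without any 1 of the cell libraries 2 clock genes were higher, the lower cathepsin call ended without cell library 2, and 1 cholesterol gene was lower without tissue library 3.

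HOX genes, which mark position along the body axis, were higher in culture in 10 of 31 measured genes and lower in 5. Genes of paralog group 11 were all higher, and hoxa11b, hoxc11a and hoxd11a were at 0 in all tissue libraries with cell means of 139, 58.1 and 66.4, while hoxa2b and hoxb2a changed by -1.69 and -2.60. Against this order, hoxc8a, the most abundant HOX gene in tissue, changed by -2.38 (adjusted p = 9.71e-05) and hoxa9b by -1.23 (adjusted p = 0.017), while HOXC8 and the other genes of group 9 were higher. Under equal totals 25 HOX genes were higher and none lower, and without cell library 1, 2 or 3 the higher ones numbered 9, 6 and 7 and the lower ones 3, 3 and 2. Across genes, the change followed the paralog group number with Spearman's rho of 0.735 and Pearson's r of 0.747 (two-sided permutation p = 1e-05 for rho, the smallest that 100000 resamples give, as 1 relation tested), and clustered genes are not independent replicates. No source of this order, such as position of origin or cell type, was tested.

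Of the names abundant in tissue, some were nearly absent from cultured cell library 1 and present in libraries 2 and 3. In the 57 such names with a tissue mean of 50000 or more, the log2 ratio to tissue had an SD of 0.375 in library 2 and 0.701 in library 3, where it ran from -1.35 to 1.79 around its median, and these SDs, on names chosen for the pattern, cannot tell own expression from carried-over RNA. Muscle RNA or reads carried into these libraries predict that less abundant names chosen the same way follow the same fraction. Names not counted as nearly absent from library 1, such as col1a2 and the fibre gene ckmb, were not part of this. Over the 29 names with a tissue mean of 5000 to 50000 that were also nearly absent from library 1, the observed sum was 1.31 times the predicted one in library 2 (95% bootstrap interval over names 0.963 to 1.73) and 1.72 times in library 3 (1.12 to 2.49), both inside the range of 0.5 to 2 set beforehand although the second interval reaches beyond it. The regulators myog (44.2, 133, 326 in cell libraries 1, 2 and 3), myod1 (39.9, 86.9, 238) and mymk (23.5, 45.2, 131), outside those names and present in library 1 too, lay far above the at most 0.29 that the fraction predicts, so carried-over RNA does not account for them, while myf5 and mef2ca were lower in library 2 than in library 1, and own expression of the fibre genes or a few mature fibres in the cultures may give the same fraction and stay open.

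Several abundant transcripts without an identified gene differed between libraries across the groups. The highest, named CT583728.14, had 760941, 467954 and 36586 in the cell libraries and 818224, 53399.6 and 60515 in the tissue libraries. A library batch shared by cells 1, cells 2 and tissue 1 could give this, but with group in the model limma called 0 transcripts for this partition and 0 for each of the other 8 that set apart 1 library of each group, so the test decided nothing. At an unadjusted p below 0.05 this partition had 3678 transcripts and the highest other had 4394. What the transcripts encode was not analysed here, and no biological explanation was tested.

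With 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. In 1 split, the real one, 30949 transcripts, 8118 names and 15 lists passed, and the highest other values were 0, 0 and 14. Every other split sets cells and tissue together on both sides, so its counts do not show what no change would give.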
